A study of Caenorhabditis elegans with 8 samples.

How the data were processed

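Total RNA from 8 worm samples was labelled with Hy3 and hybridised to 1-colour miRCURY arrays, 1 ug per array, per the labels. The labels state technical repeats and no repeat of samples, so each strain and condition had 1 array. P-values over both strains treat the strains as the samples of a condition and measure only the spread between these arrays. The scanner and image software are not given in the sources used here.

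Per the file headers, the authors deposited a foreground intensity and a foreground-minus-background intensity for each of 10080 spots per array, with 4 spots per probe. The authors' probe table equals the median of those spots for 100% of probes. The authors' normalized values are a ratio, each intensity divided by 1 constant per array (128 to 294), with values of 0 or less left empty. The constant equals the array's median of the 5 C. elegans probes that reach 50 on every array, as computed from the deposited values. The authors' deposited table also holds 16 columns of fold change, which equal ratios of those normalized values. Of these, 2 set LS292 static flight against N2 1g flight or the reverse, and so differ in strain and condition.

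The array held 2314 probe identifiers, of which 156 carried a C. elegans name and 2145 no name. No probe sequences were used here, so the names stand as the authors gave them. From the intensities, background was corrected with limma's normexp (offset 50), the log2 values of the 4 spots were averaged, and arrays were quantile normalized over the 156 named probes with limma 3.58.1 in R 4.3.3. MiRNAs with a spot-median intensity of at least 50 on 2 or more of 8 arrays were kept, which left 20. An additive limma fit of strain and condition over all arrays (3 residual degrees of freedom) gave each comparison, with Benjamini-Hochberg adjustment and a threshold of 0.05. Its residual is the interaction of strain and condition, so a real strain-specific response enters the error. Normexp with this offset placed a spot of 0 intensity at log2 7.30 to 8.34, depending on the array, which compresses differences between dim spots. Quantile normalization then set values by rank. Differences of brighter probes were compressed in some cases and enlarged in others. In LS292, miR-1823 at 612 on the centrifuge and 80 on the ground differed by log2 0.58, against 5.14-fold by the authors' values. In N2, let-7 at 479 and 367 differed by log2 0.98, against 1.23-fold by the authors' values.

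Of 18 miRNA lists fixed before the data were examined, those with 2 or more members past the filter were tested with camera (preset correlation 0.01). Named miRNAs were list members past the filter, miRNAs past the threshold in the same direction in both strains, miRNAs 2-fold apart in both strains, and within a strain up to 5 per direction detected in both arrays. MiR-787, miR-788 and miR-799, and the abundant miRNAs below the minimum, were named after their values were seen. Within-strain differences had no test.

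Tested on simulated data of 20 miRNAs with 4 changed, the fit called 97.2% of changes of log2 1 for the 1g centrifuge against ground and 99.9% for LS292 against N2. It called 1.97% and 2.12% of the others. The changes were added to normal noise on the normalized log2 scale. Background correction, the offset, quantile normalization and divergent spots were therefore not simulated. These rates give no power for a 2-fold change in intensity, which the processing can shrink. Alternatives covered background correction, normalization, the authors' values, the filter, the offset, the prior, the model terms and arrays left out. The median of spots, scaled spot medians, removal of spots with a local background over 3 times the array median, the fits without the N2 static flight array for pairs of conditions, and the fit of all 412 named and unnamed probes were added after seeing the data.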

Results

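MicroRNA levels were measured in Caenorhabditis elegans that travelled on the Shenzhou-8 spacecraft and in worms kept on the ground. The 8 arrays covered 2 strains in 4 conditions, with 1 array per strain and condition. N2 is the wild type, and LS292 carries a mutation of dys-1, the worm dystrophin gene. Worms loaded as dauer larvae, the stress-resistant larval stage, were flown for 16.5 days at 23 °C. One flight condition was static, combining space radiation (1.92 mGy) with microgravity, and the other was a 1g centrifuge, with radiation (2.27 mGy) but without weightlessness. A ground control was run in the same kind of hardware, and a further control, titled as a transport control in the labels and called the no-transport control here, stayed in an incubator without going to the launch site. The labels give no radiation dose, duration, temperature or collection time for that control. For the flight and ground control samples they give collection after 7 h. The series asked how space radiation and microgravity act together, and whether dys-1 alters the response.

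Few worm miRNAs gave signal. Names are those of the deposited file and were not checked against probe sequences, so each value belongs to the probe that carries the name. Of 156 C. elegans probes, between 11 and 19 per array had a spot-median intensity of at least 50 above local background, and 20 did so on 2 or more arrays. Only let-7, miR-84, miR-55, miR-257 and miR-1823 reached it on all 8 arrays. Let-7 and miR-84 belong to the let-7 family, which times larval transitions, and miR-55 belongs to the miR-51 family. The spot median of let-7 ranged from 128 to 655, that of miR-257 from 248.5 to 662.5 and that of miR-55 from 175 to 355.5.

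Several miRNAs that are abundant in worms lay below 50 on every array. The muscle miRNA miR-1 had a highest spot median of 11.5, the larval timing miRNA lin-4 18.5, miR-58 26.5 and miR-71, which is linked to lifespan, 12.5. The lists of stress and lifespan, diapause and starvation, muscle and intestine miRNAs had 0 members past the intensity filter, as did the miR-35 family of embryonic miRNAs, the miR-64, miR-44, miR-2, miR-46 and miR-238 families. The neuronal list kept miR-124, the epidermis and seam list miR-84, the lin-4 family miR-237, the miR-58 family miR-81 and the miR-72 family miR-73. The male-enriched list had 0 probes on the array. The let-7 family (let-7, miR-84 and miR-795) and the miR-51 family (miR-52, miR-55 and miR-56) had 3 members each past the filter and were the 2 lists tested.

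The 4 spots of a probe spread widely. For let-7 on the N2 ground array they ran from -1789 to 826, with an SD of 1179 around a median of 367. Spots more than 50 below their local background made up 23.7% of the N2 static flight array and 3.30% to 10.7% of the other arrays. Across the 20 miRNAs, Pearson correlations between arrays ranged from 0.13 to 0.92. These correlations are across miRNAs, which are not independent replicates. The number of arrays limits the precision of every comparison.

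**Figure D1:**
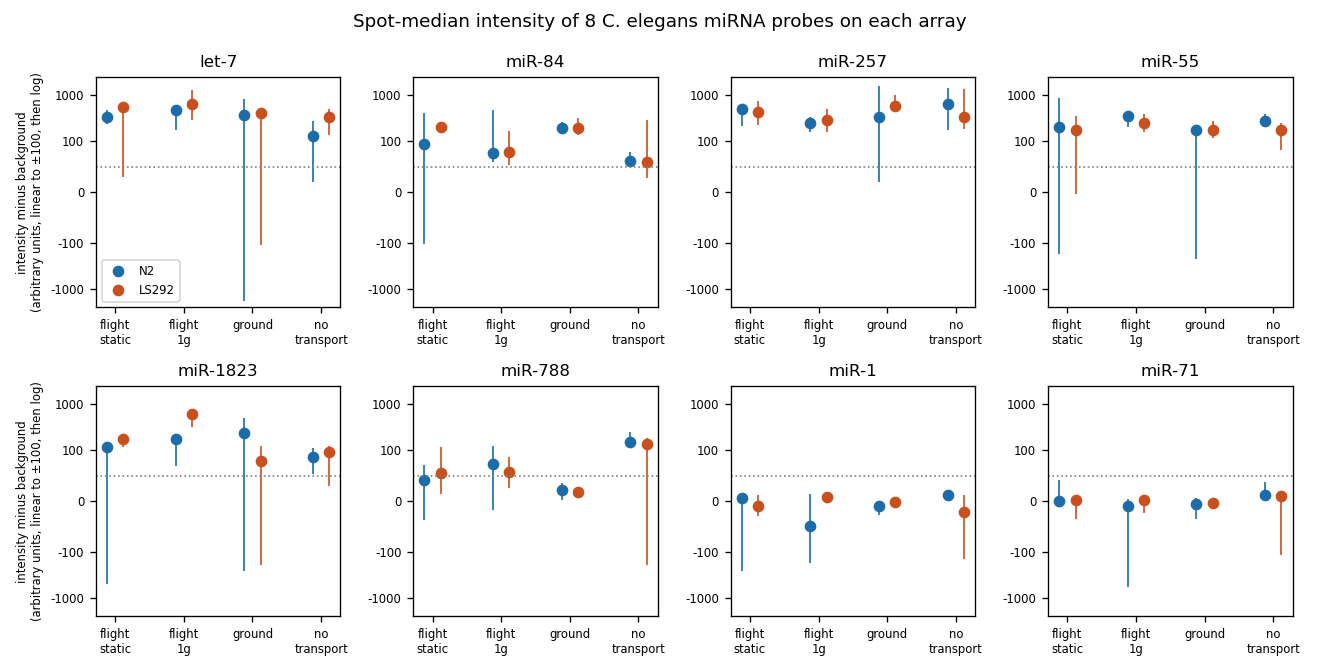
Spot-median intensity minus local background (vertical axis, arbitrary units, linear to ±100 and logarithmic beyond) of 8 miRNA probes on each array, by condition (horizontal axis), for N2 (blue) and LS292 (orange). Points are medians of 4 spots, vertical lines run from the lowest to the highest spot, and the dotted line marks 50; miR-1 and miR-71 lie below it on all 8 arrays, while miR-788 lies above it on both no-transport arrays (151 and 137).

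Static flight was compared with the ground control for the joint effect of radiation and microgravity. No miRNA passed the threshold: limma called 0 of 20 at an adjusted p under 0.05, and 0 had an unadjusted p under 0.05. Let-7 differed by log2 0.29 (SE 0.22) and miR-84 by -0.15 (SE 0.19), both with an adjusted p of 0.991. Over all alternatives let-7 ranged from -0.35 without high-background spots to 1.20 with background subtraction, and was 0.07 without the N2 static flight array. MiR-84 ranged from -1.28 with background subtraction to 0.0089 without that array. The let-7 family had 1 member with a positive and 2 with a negative difference, and the miR-51 family 2 and 1. Neither list passed (camera adjusted p 0.893 and 0.509), and 0 members passed when adjusted over the list alone. Of 20 miRNAs, 4 had the same direction in both strains, 12 had opposite directions and 4 had a difference of exactly 0 in at least one strain. The Pearson correlation of the strains' differences across miRNAs was -0.45. In N2, miR-55 was 0.53 and miR-1823 was -0.58 on the log2 scale relative to ground. In LS292, miR-1823 was 0.28 and miR-230 was -0.39.

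The 1g centrifuge flight was compared with the ground control for the effect of flight without weightlessness. MiR-257 was lower in both strains, by log2 -0.77 (SE 0.11, limma adjusted p 0.0095), and was the 1 miRNA of 20 past the threshold. Its spot medians were 248.5 in flight and 331.5 on the ground in N2, and 294 and 603 in LS292. On both 1g arrays let-7 held the top quantile value, 9.08, which miR-257 held on both ground arrays, so their differences are not independent. Let-7 differed by 0.70 (SE 0.22, adjusted p 0.191) and was one of 4 miRNAs with an unadjusted p under 0.05. It passed with a trended robust prior (adjusted p 0.0404). Its difference was 0.16 with the median of spots, 0.19 without high-background spots, 0.20 with the authors' values and 1.78 with background subtraction. The let-7 and miR-51 families each had 1 positive and 2 negative members, with 0 past the threshold over all miRNAs or adjusted over the list alone (camera adjusted p 0.865 for both). MiR-84 had spot medians of 76.5 and 80 on the centrifuge and 190.5 and 197.5 on the ground, with a log2 difference of -0.35 (adjusted p 0.496). That difference was -0.64 with scaled spot medians, -0.97 without high-background spots (adjusted p 0.0984), -1.64 with the authors' values and -1.79 with background subtraction, and passed under none of the alternatives. The miR-257 call ended when the median of the 4 spots replaced their mean (log2 -0.44, SE 0.29, adjusted p 0.512). It also ended, with differences as large as or larger than -0.77, with background subtraction (-1.38), the authors' values (-1.05) and the 4 arrays alone (-0.77). It ended with smaller differences with high-background spots left out (-0.50) and scaled spot medians (-0.35), and adjusted p ranged from 4.28e-06 to 0.628 over all alternatives.

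Static flight was compared with the 1g centrifuge for the effect of microgravity within the flight. The 2 conditions also differed in radiation dose (1.92 and 2.27 mGy) and in centrifugation itself. MiR-257 was higher in static flight by log2 0.77 (SE 0.11, limma adjusted p 0.0095), the only one of 20 past the threshold and the only one with an unadjusted p under 0.05. Its static spot medians were 505 in N2 and 443 in LS292. Let-7 differed by -0.41 (SE 0.22, adjusted p 0.619), by -0.63 without the N2 static flight array, -0.16 with the median of spots and 0.042 with the authors' values. The let-7 family had 2 positive members and the miR-51 family 2, each of 3, and 0 passed over all miRNAs or adjusted over the list alone (camera adjusted p 0.847 for both). The miR-257 call ended with median scaling (log2 0.49, SE 0.28, adjusted p 0.476), with the median of the spots (log2 0.63, SE 0.29, adjusted p 0.487), without high-background spots (0.50) and with scaled spot medians (0.59). It ended with a difference as large or larger with the 4 arrays alone (0.77), the authors' values (1.22) and background subtraction (1.38). Its adjusted p ran from 4.28e-06 to 0.579 over all alternatives. Without the N2 static flight array, which leaves 1 static array, the difference was 0.80. Quantile normalization gave miR-257 one top value, 9.08, on 6 of the 8 arrays, so its fitted spread is small by construction. These include the static flight and ground arrays, so on the main scale this call repeats the call against ground with the sign reversed.

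The ground control was compared with the no-transport control for what transport and the hardware add. Limma called 0 of 20 miRNAs, with 1 at an unadjusted p under 0.05 (miR-787, log2 -0.45, SE 0.13, adjusted p 0.235). MiR-787 passed with scaled spot medians (-1.56, adjusted p 0.0490), and was -1.002 without high-background spots, -1.41 with background subtraction and -1.86 with the authors' values. All 3 let-7 family members had positive differences, of which miR-84 had the largest (log2 0.46, adjusted p 0.328). The miR-84 difference ranged from 0.26 with median scaling to 2.40 with background subtraction. The list did not pass (camera adjusted p 0.222), and 0 members passed adjusted over the list alone. The miR-51 family had 1 positive and 2 negative members (camera adjusted p 0.623) and also 0 passing adjusted over the list alone. MiR-788, singled out after its values were seen, had spot medians of 23 and 18 in the ground control, below the minimum of 50, and 151 and 137 without transport, so the size of its difference was not measured. Its fitted log2 difference was -0.26 (adjusted p 0.328), with no call. It passed under 4 alternatives: scaled spot medians (-2.15, SE 0.30, adjusted p 0.0062), the authors' values (-3.35, adjusted p 0.0079), the median of spots (-0.41, adjusted p 0.0233) and without high-background spots (-1.20, adjusted p 0.0218). Its adjusted p ranged from 0.0062 to 0.633 over all alternatives.

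Both flight conditions together were set against both ground conditions. Limma called 0 of 20 miRNAs, with 3 at an unadjusted p under 0.05. Let-7 had a difference of log2 0.53 (SE 0.15, adjusted p 0.140) and was the 1 member of its family that passed adjusted over the list alone, and 0 of the miR-51 family did. The let-7 difference was 0.86 in N2 and 0.20 in LS292, and both 1g arrays held the top quantile value, 9.08. Over all miRNAs let-7 passed with the filter on all 8 arrays (adjusted p 0.0487) and a trended robust prior (adjusted p 0.0241). Its difference was 0.17 without high-background spots, 0.26 with the median of spots and 1.43 with background subtraction. MiR-257 had a difference of -0.38 (SE 0.08, adjusted p 0.0567). Neither list passed (camera adjusted p 0.639 and 0.996). On the main scale miR-257 was 9.08 on every static flight, ground and no-transport array, so its difference came from the 1g arrays alone. MiR-257 passed with median scaling (log2 -0.82, adjusted p 0.00195) and under 4 other settings, which kept the same quantile values. Its adjusted p ran from 0.000233 to 0.990 over all alternatives. It also passed without either 1g array (-0.42 and -0.35), where the SE fell from 0.08 to 0.02 because nearly all values left were equal.

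LS292 was compared with N2 across the 4 conditions for the effect of the dys-1 mutation. Limma called 0 of 20 miRNAs, and 0 had an unadjusted p under 0.05. Let-7 differed by log2 0.33 (SE 0.15, adjusted p 0.901) and miR-84 by 0.06 (SE 0.14, adjusted p 0.947), and the direction of both turned under some settings. The let-7 difference was 0.19 without either no-transport array and ranged from -0.021 without high-background spots to 0.57 with the authors' values. The let-7 family had 2 positive of 3 members and the miR-51 family 0, with 0 past the threshold adjusted over the list alone (camera adjusted p 0.292 and 0.311). With an estimated correlation, 0 lists passed in any of the 6 comparisons.

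Within each strain a difference rests on 2 arrays and has no replicate check. No miRNA detected in both arrays was 2-fold apart in any of the 8 within-strain comparisons on the quantile-normalized scale. That scale can compress or enlarge differences, and with the authors' values these counts ran from 0 to 5. Some miRNAs below 50 on 1 array of the pair did differ 2-fold. N2 miR-258 was log2 -1.07 for static flight against ground and 1.03 for ground against no transport. LS292 miR-73 was 1.01 for the centrifuge against ground and -1.07 for static flight against the centrifuge. Its spot medians were 554.5 on the centrifuge, 18 on the ground and 10 in static flight. In LS292, miR-1823 had spot medians of 612 on the centrifuge and 80 on the ground, a normalized log2 difference of 0.58. In N2, let-7 had spot medians of 479 and 367 in the same comparison, 1.23-fold by the authors' values, yet a normalized log2 difference of 0.98. That value averages 4 spots, which ran from -1789 to 826 on the ground array, and the 1g array held the top normalized value, 9.08. The strains' differences had Pearson correlations across the 20 miRNAs of 0.31 for the centrifuge against ground, 0.38 for static against centrifuge and 0.19 for ground against no transport.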

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

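The tests in this part were chosen or their reading was set after the results were seen, except the recount without high-background spots and the background subtraction for miR-788.

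Probes without a name, which the main tests of the report do not use, carried signal: 158 of 2145 reached 50 on all 8 arrays, against 5 of 156 named probes. The brightest unnamed probe had a spot median of 6185.5 to 24205.5, depending on the array. The brightest named probe reached 662.5 on any array. Failed labelling or hybridisation of whole arrays stays open: those 158 probes speak against it, but what they detect is not known, and spike-in control medians of -8 to 19 lay near those of empty spots (-1.5 to 3). Local background hiding the spots is argued against, because 0 of 7 abundant miRNAs (miR-1, lin-4, miR-58, miR-71, miR-228, miR-60 and miR-80) reached 50 on 2 arrays once high-background spots were left out. Signal that is not specific to the worm names stays open: the odds ratio of named over unnamed probes was 0.417 (Fisher's exact test, two-sided p 0.0515), and names attached to the wrong probes, which would change what every named value measures, were not tested. No biological explanation was tested.

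MiR-257 differed between the 1g centrifuge and both static flight and ground control. On the main scale both calls are the same result, since the static flight and ground arrays held equal values. Equal top values from quantile normalization stay open as a cause for the ground comparison. Median scaling kept the call (log2 -0.90, SE 0.28, limma adjusted p 0.0395), but its 5 scaling probes include miR-257. Its SE was also the same for let-7, miR-84 and miR-257. Scaled spot medians (-0.35, SE 0.50) and the authors' values (-1.05, SE 0.64) lost the call (adjusted p 0.628 and 0.544). Equal top values stay open for static flight too. There the adjusted p under median scaling was 0.476, since the difference went from log2 0.77 (SE 0.11) to 0.49 (SE 0.28). Divergent spots stay open for both: with the median of spots the differences were -0.44 and 0.63, and the adjusted p of 0.512 and 0.487 came with an SE that rose to 0.29. An effect of the centrifuge or of gravity stays open and untested.

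MiR-788 was lower in the ground control than without transport when spot medians were scaled (log2 -2.15, SE 0.30). A differing background level is argued against as the whole cause. After each array's median named probe was subtracted, with the scaling to bright probes kept, the fitted difference was -2.03 (SE 0.32, limma adjusted p 0.0105). The ground spot medians lie below 50, but even with them raised to 50 the gap in intensity was 101 in N2 and 87 in LS292, against shifts of the named median of 25.8 and 11.8. A single brightness factor for whole arrays is argued against too. With ground values raised to 50, the log2 ratio of ground over no transport was -1.59 in N2 and -1.45 in LS292. The 163 probes bright on all arrays had median log2 ratios of 1.08 and 0.62, the opposite direction. With arrays centred the fitted difference was -1.84 (SE 0.51, limma adjusted p 0.0124). An array difference that varies with intensity stays open. Quantile normalization over all 2301 named and unnamed probes, with the 412 past the filter fitted, gave -0.35 (limma adjusted p 0.257). Transport, hardware, site and timing were confounded in this comparison and are untested.

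The strains moved in opposite directions for 13 values among named miRNAs detected on all 4 arrays concerned, and the differences were not tested. With 1 array per strain and condition an opposite sign is easily met by chance. A minimum of log2 0.25 in both strains would leave 3 of these and one of 0.5 would leave 0; no minimum was applied, since 0.5 and 0.25 were both considered after the values were seen. For static flight against ground, LS292 minus N2 was 0.86 for miR-1823, -0.36 for miR-56 and -0.89 for miR-230. For the 1g centrifuge against ground it was 0.80 for miR-258, 0.78 for miR-1823, -0.28 for miR-81 and -0.95 for miR-55. For static flight against the centrifuge it was 0.42 for miR-55, 0.28 for miR-237 and 0.67 for miR-84. For ground against no transport it was 0.75 for miR-230, 0.17 for miR-52 and -0.44 for miR-1823.

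Other splits of the 8 arrays say nothing about the 2 comparisons of 4 arrays against 4, because the real count was 0 in both. All 32 splits that could be fitted beside condition gave as many miRNAs as the strains did (highest other 1), and so did all 34 beside strain for flight (highest other 0).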

How the results depend on the processing

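The median of spots, scaled spot medians, removal of high-background spots and the pairwise fits without the N2 static flight array were chosen after seeing the data. No paired analysis was possible because a replicate number pairs no arrays where each strain and condition has 1; the main fit already sets conditions against each other within strains. The count for static flight against ground stayed 0, and that for LS292 against N2 stayed 0, under every alternative run for them. Signal over background limits all results, since only 5 miRNAs reached 50 on all arrays.

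For the 1g centrifuge against ground, the count of miRNAs past the threshold went from 1 to 0 with background subtraction, the authors' values, the median of spots, scaled spot medians, without high-background spots and with the 4 arrays alone (fewer arrays), and to 2 (let-7 and miR-257) with a trended robust prior. For static flight against the centrifuge it went from 1 to 3 with background subtraction (miR-255, miR-73 and miR-81 in place of miR-257, which lost its call) and to 0 with median scaling, the authors' values, the median of spots, scaled spot medians, without high-background spots and with the 4 arrays alone. For ground against no transport it went from 0 to 1 (miR-788 each time) with the authors' values, the median of spots and without high-background spots, and to 3 (miR-787, miR-788 and miR-799) with scaled spot medians. For flight against non-flight it went from 0 to 1 (miR-257) with median scaling, no filter and no strain term, and to 2 (let-7 and miR-257) with the filter on all 8 arrays (fewer miRNAs tested) and a trended robust prior; leaving out single arrays gave 0 to 1. Lists past the threshold went from 0 to 1 in ground against no transport with no filter, and stayed 0 otherwise. The 3 miRNAs called with background subtraction in static flight against the centrifuge had static spot medians below 50 in N2 and LS292. These were -83 and 21 for miR-255, -71.5 and 10 for miR-73, and 28.5 and -28 for miR-81. That setting put spots under 1 at 1, which can enlarge such differences. Without the N2 static flight array only 1 static array is left, so for this comparison only the difference is given. Where no construction is named, the cause was not tested.

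Counts of miRNAs 2-fold apart within a strain, among those detected in both arrays, were 0 in the main setting and depended on the setting. With background subtraction they were 5, 6, 5 and 5 in N2 (static against ground, centrifuge against ground, static against centrifuge, ground against no transport) and 4, 5, 5 and 5 in LS292. With the authors' values they were 0, 3, 2 and 5 in N2 and 3, 3, 5 and 2 in LS292. With scaled spot medians they were 1, 2, 1 and 3 in N2 and 0, 1, 1 and 1 in LS292. Without high-background spots they were 1, 1, 0 and 2 in N2 and 0, 3, 1 and 2 in LS292. The N2 centrifuge count was 1 with offset 10, the LS292 centrifuge count 2 with median scaling, and the N2 ground against no transport count 1 with the median of spots. The cause was not tested.

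Directions turned for let-7 without high-background spots, to log2 -0.35 in static flight against ground and -0.021 in LS292 against N2, and to 0.042 with the authors' values in static flight against the centrifuge. MiR-84 turned to 0.0089 in static flight against ground without the N2 static flight array. In LS292 against N2 it turned to -0.036 with median scaling, and it ranged from -0.027 to 0.21 as arrays were left out, with -0.027 without both no-transport arrays and -0.018 without both static flight arrays. Of the single-miRNA values, 14 lost and 15 gained the call.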

Other observations

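The fit of all 412 named and unnamed probes, which was added after seeing the data, gave the most calls between the ground and no-transport controls. With scaled spot medians limma called 28 probes, 3 higher and 25 lower in the ground control, beside a median log2 difference of -0.31 over all probes. MiR-788 and miR-799 were the 2 named miRNAs among them. With quantile normalization the count was 5, with 4 higher and 1 lower. MiR-799 had spot medians of 34 and 32.5 in the ground control and 116 and 111.5 without transport. For the 1g centrifuge against ground the counts were 5 and 1, and the other 4 comparisons gave 0 in both ways, with 11 to 46 probes at an unadjusted p under 0.05.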
